A study of Mus musculus with 12 samples.

How the data were processed

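Gene expression was measured in 12 samples of mouse central nervous system tissue with Affymetrix arrays, which hold sets of short probes near the 3′ end of transcripts. The labels place 3 samples in each of 4 groups: wild-type and NR3B knockout mice at postnatal day 0 (P0) and at postnatal day 5 (P5). NR3B is read here as the usual protein name of the NMDA receptor subunit encoded by Grin3b. The labels describe the tissue as brain, hindbrain and spinal cord in one field and as brain in another, and the share of each part in a sample is not given in the sources used here. The labels number the samples of a group but do not say that they came from separate animals, so p-values measure the spread between these samples, which may be technical in part. In P0 wild type, P0 knockout and P5 knockout, samples of a group differed in Xist, which marks female tissue, and in Y-linked Eif2s3y. Not all samples of these groups therefore came from the same animal, while for P5 wild type this stays open.

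The values are probe set signals, an intensity on a linear scale, as deposited by the authors in the series table. The software that made these signals is not given in the sources used here. On every array, the mean signal after leaving out the highest and lowest 2% of probe sets was 2500.01, so each array had been scaled by a single factor. No detection calls or probe-level values were used here. For arrays, the number of arrays limits the precision, and 3 per group is a small number.

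Of 45101 probe sets, 64 control probe sets were left out. The platform annotation gave a single gene symbol for 34945 of the others, several symbols for 932 and none for 9160. Through the gene identifier, 34741 of the single symbols were found in the RefSeq gene table of mouse assembly GRCm38.p6, and 0 symbols changed by that update. The table was used for names and for which genes neighbour each other, and no coordinates were taken from it.

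Signals were transformed as log2(signal + 16). The arrays' median log2 signals spread over 0.273, more than the limit of 0.1 set in advance for keeping the deposited scaling, so arrays were quantile-normalized. Probe sets with a mean below the 40th percentile were left out, and each gene was represented by its probe set with the highest mean, which left 12600 of 18193 genes. A linear model with a mean per group was fitted to all 12 samples with limma 3.58.1 in R 4.3.3, with an intensity-dependent prior in the empirical Bayes step. It gave 8 residual degrees of freedom and 5.63 prior degrees of freedom. The 6 comparisons were knockout minus wild type at P0, at P5 and averaged over both ages, P5 minus P0 in wild type and in knockout, and the genotype by age interaction. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were counted as changed, and every adjusted p for a gene comes from limma. Differences are log2 differences on the log2(signal + 16) scale, which understates the change of dim genes, and a fold is 2 to the power of the size of that difference. Single probe sets, such as that of the targeted gene, were taken from the same fit with no filter on dim probe sets, and a two-sided exact permutation test of the samples' labels was run on them.

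Before the data were examined, 37 gene lists were fixed for receptors, synapses, cell types, brain regions, cellular processes, sex and the neighbours of Grin3b on its chromosome. They hold 779 entries, of which 595 were tested, 99 lay below the filter and 85 had no probe set with that single symbol. Lists were tested with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with the correlation estimated for each list. The fry test, which asks whether the members of a list move on balance in a single direction, was run beside them. Members were also counted with adjustment over the list alone.

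The genes named in the text follow a rule fixed before the data were examined. They are the targeted gene, the 10 largest rises and the 10 largest falls per comparison among changed genes whose samples did not overlap between the groups, up to 4 members with the smallest p in each list discussed, and all measured NMDA receptor subunits. Where fewer than 5 genes passed the threshold, the 5 genes with the smallest p were taken. Any other gene named was chosen after its values were seen, and the text says so.

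The gene tests were tested on simulated data made from the real genes' means and spreads, with 200 of 12600 genes changed. Of the genes changed by 2-fold, 68% were recovered in knockout minus wild type at P0, 74% at P5, 84% in the average over both ages, 76% in P5 minus P0 in wild type, 78% in knockout and 46% in the interaction. Of genes changed by 4-fold, 98%, 94%, 100%, 94%, 98% and 92% were recovered in the same order. False calls numbered 47, 2, 11, 8, 12 and 9 in that order. The 47 belong to the P0 comparison, in which the spread between samples is larger than the spread shared by all groups in the fit. With no simulated effect, 2, 0, 1, 0, 0 and 1 genes were called, and a single list shifted by 1 on the log2 scale was the 1 list called. The simulated noise was independent between genes. In the real samples a single component held 36.5% of the within-group variance, so these rates may not carry over to them.

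The alternatives fixed in advance were offsets of 1 and 64, the deposited scaling and median centring in place of quantile normalization, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, each probe set on its own, only the samples of the groups compared, other settings of the empirical Bayes step, array weights, the replicate number as a block, Xist as a covariate, a plain t-test per gene, and leaving out each sample in turn. A covariate from the spread within groups and a fit without P0 wild-type samples 1 and 2 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.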

Results

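Expression was compared between wild-type mice and mice lacking NR3B, an NMDA receptor subunit, in brain, hindbrain and spinal cord tissue taken at birth (P0) and at postnatal day 5 (P5). Each of the 4 groups held 3 samples, and each sample was read on its own array. Median signals ranged from 607 to 737 over the 12 arrays after the deposited scaling. Samples of a group resembled each other more at P5 than at P0. The median gene had a within-group SD on the log2 scale of 0.119 in P5 wild type and 0.133 in P5 knockout, against 0.269 in P0 wild type and 0.210 in P0 knockout (n = 3 each). The first principal component held 45.4% of the variance and placed all 6 P5 samples apart from the 6 P0 samples. Along the second component, with 17.1%, the P0 samples spread from 23.8 for wild-type sample 1 to -29.3 for knockout sample 3, and wild-type sample 2, at -22.4, lay beside knockout samples 2 and 3. P0 wild-type sample 1 also had an 18S ribosomal RNA signal of 7728, against 48911 to 110512 in the other 11 samples.

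**Figure D1:**
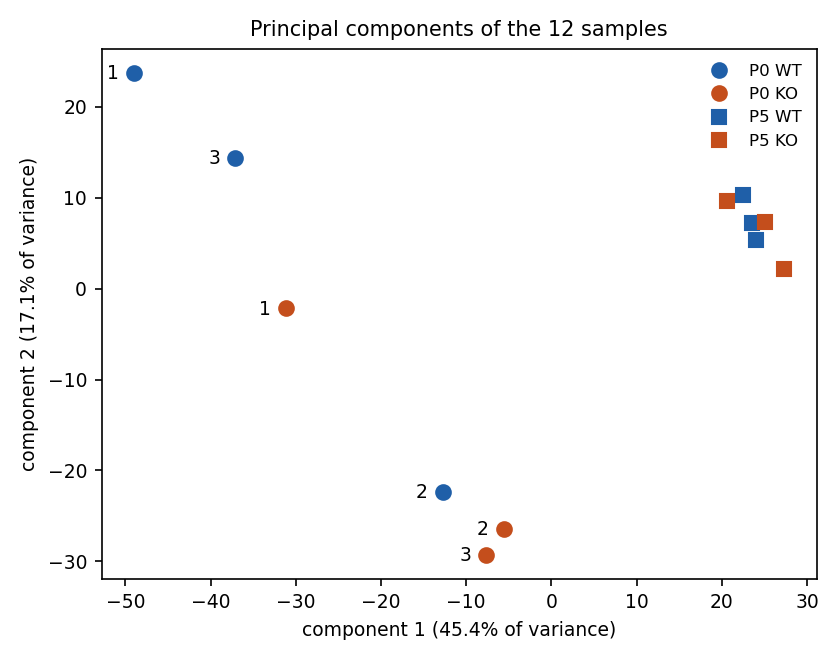
Scores of the 12 samples on the first and second principal components of the 12600 tested genes (log2 scale, axes with their share of the variance). Circles are P0 and squares P5, blue is wild type and orange knockout, and digits are the replicate numbers of the P0 samples; the P5 samples lie close together and the P0 samples spread along both axes.

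The transcript of the targeted gene was lower in the knockout samples at both ages. The only Grin3b probe set (1449899_at) read 285 ± 79.3 in P0 wild type and 55.7 ± 35.9 in P0 knockout, and 199 ± 64.8 in P5 wild type and 44.5 ± 4.44 in P5 knockout (signal, mean ± SD, n = 3 each). All wild-type samples lay above all knockout samples at each age. The log2 difference was -2.11 (SE 0.49) at P0 and -1.75 (SE 0.49) at P5, and the average over both ages was -1.93 (SE 0.35), or 3.81-fold lower. The exact permutation p was 0.1 at P0, 0.1 at P5 and 0.005 for the average, each the smallest that the design allows. The probe set is dim, with a mean at the 13th percentile of all probe sets and below the filter, and among all probe sets the adjusted p was 0.359, 1 and 0.237 in the same order. At P0 it passed the threshold without P0 wild-type sample 2 (adjusted p = 0.0293, against 0.0293 to 0.682 over 16 alternatives). The labels do not give the deleted part of the gene, so whether this probe set lies inside it is open.

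No other NMDA receptor subunit that was read here differed between the genotypes past the threshold, and Grin1 was not among those read. Of the other subunits of these receptors, which are glutamate-gated cation channels, Grin2b, Grin2d and Grin3a were bright enough to be tested. Knockout minus wild type at P0 was -0.12 (SE 0.17) for Grin2b, 0.37 (SE 0.25) for Grin2d and 0.16 (SE 0.21) for Grin3a, with an adjusted p of 0.739, 0.444 and 0.69. At P5 it was 0.09 for Grin2b, -0.13 for Grin2d and 0.00 for Grin3a with the same errors, and the adjusted p was 1 for each. Grin2a and Grin2c lay below the filter, at -0.49 (SE 0.42) and 0.05 (SE 0.35) at P0 and at -0.18 and 0.56 at P5. The estrogen-related receptors Esrra, Esrrb and Esrrg, nuclear receptors that also carry the code NR3B, held no changed member in any comparison of the genotypes.

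**Figure D2:**
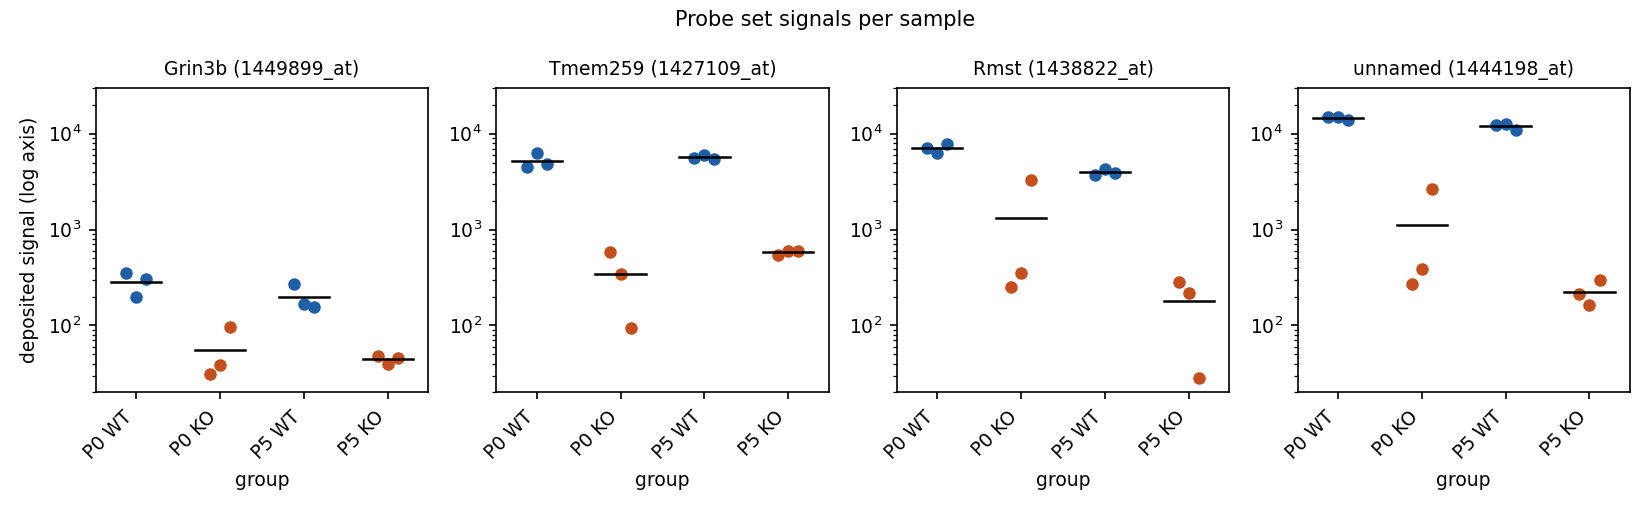
Deposited signal (log axis) of 4 probe sets in each sample, by group; blue points are wild type, orange points knockout, and black lines group means of 3 samples. Wild-type samples lie above knockout samples for Grin3b, Tmem259, Rmst and the unnamed probe set 1444198_at at both ages, and P0 knockout sample 3 lies between the groups for Rmst (3316) and for 1444198_at (2674).

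At P0, the largest genotype difference among tested genes was in Tmem259, a gene that encodes a membrane protein and lies next to Grin3b. Its log2 level fell from 12.31 ± 0.30 in wild type to 8.17 ± 1.14 in knockout (SD, n = 3 each), a difference of -4.14 (SE 0.39) and 17.6-fold (adjusted p = 0.000724), with the knockout level under the 8.72 of the filter. Hnrnpl, an RNA-binding protein that regulates splicing, rose 2.32-fold, from 12.07 ± 0.36 to 13.28 ± 0.03 (adjusted p = 0.0269). Apod, a lipid-binding apolipoprotein of glia and fibroblasts, rose 2.06-fold, from 12.39 ± 0.28 to 13.43 ± 0.16 (adjusted p = 0.0269). These were the 3 changed genes of 12600, 2 higher and 1 lower. Under 2 of the alternatives, among them the fit to the P0 samples only, 0 genes passed. The adjusted p of Tmem259 was 1.11e-05 to 0.758 over 28 alternatives, and it passed in 26. All 3 separated the samples of the genotypes completely, as did 10.1% of all tested genes, where chance gives 10%. The next genes by p did not pass: Igf2 was 0.89 (SE 0.16) higher at an adjusted p of 0.173, and Ptgds, a prostaglandin synthase of the meninges, was 1.04 (SE 0.19) higher at 0.175. A second Igf2 probe set gave -0.20 (SE 0.30). An unadjusted p under 0.05 was reached by 2032 genes in the fit that shares the spread of all groups and by 755 with only the P0 samples in the fit, against 630 expected by chance, so a shift of many genes is not shown. Of the 53 measured genes next to Grin3b on its chromosome, Tmem259 was the only changed member at P0, at P5 and in the average over both ages.

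As gene groups at P0, markers of several non-neuronal cell types were higher in the knockout samples, with 0 members past the threshold over all genes. Markers of meninges, pericytes and fibroblasts were higher by 0.41 ± 0.42 (mean log2 difference ± SD over 23 members; camera adjusted p = 0.00125), with 0 members changed and 8 higher when adjusted over the list alone, among them Igf2, Ptgds, Igfbp2 at 0.71 and Slc6a13 at 1.05. The call was lost at adjusted p = 0.606 with an estimated correlation. Red blood cell genes were higher by 0.80 ± 0.65 (5 members; adjusted p = 0.021), with Alas2, the first enzyme of heme synthesis in red cells, at 1.51 (SE 0.31) and the beta globin Hbb-b2 at 1.37 (SE 0.39). Over the list alone 4 members passed, and adjusted p = 0.819 with an estimated correlation. Microglial genes were higher by 0.40 ± 0.34 (18 members; adjusted p = 0.0298, and adjusted p = 0.852 with an estimated correlation), with the complement subunits C1qb at 0.80, C1qa at 0.78 and C1qc at 0.75, and 2 members passing over the list alone. Oxidative phosphorylation genes were higher by 0.32 ± 0.25 (28 members; adjusted p = 0.021, and adjusted p = 0.852 with an estimated correlation), with Ndufa4 at 0.70 and Cox5a at 0.52 and 0 members passing over the list alone. GABA and glycine receptor subunits, which form inhibitory chloride channels, were lower by -0.17 ± 0.22 (14 members; adjusted p = 0.021, and adjusted p = 0.384 with an estimated correlation), with Gabrg3 at -0.64 and Gabra2 at -0.49 and 0 members passing over the list alone. These were 5 of 37 lists, and with fry 2 passed, meninges and GABA and glycine receptors (adjusted p = 0.0314 each), while red blood cells (0.234), microglia and oxidative phosphorylation (0.46 each) did not. Without P0 wild-type samples 1 and 2, the samples that stood apart in 18S signal and in spread, the mean was 0.22 for meninges (adjusted p = 0.576), 0.92 for red blood cells (0.072), 0.55 for microglia (0.00635), 0.44 for oxidative phosphorylation (0.00635) and -0.15 for GABA and glycine receptors (0.312). That setting, chosen after seeing the data, leaves a single P0 wild-type sample, which is assumed to vary like the samples of the other groups. The sample left was low in Xist (signal 238.6), while P0 knockout samples 1 and 2 were high (16450 and 20890). The sexes are therefore not balanced between the P0 genotypes in that setting. Hox genes, markers of position in hindbrain and spinal cord that did not pass with all samples, were 0.54 higher in knockout there. The number of lists past the threshold was 1 without wild-type sample 1, 2 without wild-type sample 2 or 3, and 3 without knockout sample 1 or 2.

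Only Tmem259 kept its P0 call whichever sample was left out. Hnrnpl lost it without P0 wild-type sample 3, any of the 3 P0 knockout samples, P5 wild-type sample 1 or 2 or P5 knockout sample 1 or 2 (adjusted p 0.0578 to 0.177), and Apod without any of the 3 P0 knockout samples or any of the 6 P5 samples (0.0567 to 0.205). The number of changed genes was 2696 without P0 wild-type sample 2, 5 without P0 wild-type sample 1, 1 without P0 knockout sample 2, P5 wild-type sample 1 or 2 or P5 knockout sample 1 or 2, and 564 without P0 wild-type samples 1 and 2 together. In that last fit 1 P0 wild-type sample is left, which is assumed to vary like the others. It was low in Xist, unlike P0 knockout samples 1 and 2.

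At P5, Tmem259 was again lower in the knockout samples and was the only changed gene in the fit that shares the spread of all groups. Its log2 level fell from 12.46 ± 0.07 to 9.22 ± 0.11 (SD, n = 3 each), a difference of -3.24 (SE 0.39) and 9.43-fold (adjusted p = 0.0134). Rmst, a long noncoding RNA of the developing midbrain and hindbrain, differed by -4.74 (SE 0.82), with a signal of 3965 ± 270.2 in wild type and 178 ± 134 in knockout, at an adjusted p of 0.319. The probe set annotated as Gm3515, a symbol that the RefSeq table lists as a synonym of Rmst, differed by -1.47 (SE 0.27; adjusted p = 0.334), and a second Rmst probe set by -0.49 (SE 0.30). Uba7, an enzyme that activates the ubiquitin-like protein Isg15, was at 1.25 (SE 0.23; adjusted p = 0.334), with its other probe sets at -0.24 and -0.56, and the calcium-binding Efhd2 was at -0.79 (SE 0.16; adjusted p = 0.578). The shared spread includes that of the P0 samples, which is larger than at P5, and with only the P5 samples in the fit 6 genes passed. Over 27 alternatives Rmst passed in 3 (lowest adjusted p 0.00225), Gm3515 in 4 (0.000302) and Efhd2 in 3 (0.000422), and Uba7 passed in 1 of 26. An unadjusted p under 0.05 was reached by 232 genes in the fit that shares the spread of all groups and by 875 with only the P5 samples in the fit, against 630 expected by chance. Of all genes, 12.9% of genes separated the genotypes, against 10% by chance. Without any 1 of the 6 P5 samples or P0 wild-type sample 3, Tmem259 had an adjusted p of 0.0523 to 0.138 and 0 genes were called, and without P0 knockout sample 3 there were 3.

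Small shifts of whole lists passed camera at P5, none with a changed member over all genes or over the list alone, and with fry 0 lists passed (adjusted p = 0.929 for each named here). Microglial genes were higher by 0.26 ± 0.17 (18 members; camera adjusted p = 5.27e-05), with Csf1r, the receptor on which microglia depend, at 0.25 and the lysosomal Cd68 at 0.55, and adjusted p = 0.719 with an estimated correlation. Motor neuron genes were lower by -0.12 ± 0.23 (14 members; adjusted p = 0.0219), with the transcription factor Isl1 at -0.65 and Slc18a3, the vesicular acetylcholine transporter, at -0.27, and adjusted p = 0.533 with an estimated correlation. Voltage-gated ion channels were lower by -0.10 ± 0.11 (17 members; adjusted p = 0.0219), with Kcnab2 at -0.28 and Scn2b at -0.18, and adjusted p = 0.533 with an estimated correlation. Cholesterol synthesis genes were lower by -0.09 ± 0.11 (21 members; adjusted p = 0.0219), with Hsd17b7 at -0.30 and Dhcr7 at -0.28, and adjusted p = 0.726 with an estimated correlation. The number of such lists was 1 without P5 wild-type sample 1 or 3, 7 without P5 wild-type sample 2 and 2 without P5 knockout sample 1.

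Averaged over both ages, 3 genes differed by genotype, 1 higher and 2 lower. Tmem259 fell 12.9-fold (log2 difference -3.69, SE 0.28; adjusted p = 4e-05), and Rmst fell 16.6-fold (log2 difference -4.05, SE 0.58; adjusted p = 0.029). The size of both folds is uncertain, since the Tmem259 level in P0 knockout (8.17) and the Rmst level in P5 knockout (7.21) lie under the 8.72 of the filter. The Rmst fold is also that of 1 probe set. A second Rmst probe set was at -0.69 (SE 0.21) and that of Gm3515 at -0.97 (SE 0.19), both much smaller falls. Hnrnpl rose 1.83-fold (log2 difference 0.87, SE 0.12; adjusted p = 0.029). Every wild-type sample lay above every knockout sample of its age for Tmem259 and Rmst. In P0 knockout sample 3 the Rmst signal was 3316, against 250.6 and 352.3 in the other knockout samples and 6227 to 7884 in P0 wild type. Uba7 at 1.02 (SE 0.16; adjusted p = 0.0777) and Hddc3, a nucleotide pyrophosphohydrolase, at 1.71 (SE 0.30; adjusted p = 0.155) did not pass, and a second Hddc3 probe set was at -0.53. An unadjusted p under 0.05 was reached by 1092 genes, where chance gives 630. Tmem259 kept its call without any sample in turn. Hnrnpl kept it only without P0 wild-type sample 1 or 2 (0.0547 to 0.131 without the others). Rmst kept it only without P0 wild-type sample 2 or P0 knockout sample 3 (0.053 to 0.139 without the others). The count was 752 without P0 wild-type sample 2, 45 without P0 wild-type samples 1 and 2 (1 P0 wild-type sample left), and 1 without P0 wild-type sample 3, P0 knockout sample 1 or 2, P5 wild-type sample 1 or 2 or any of the 3 P5 knockout samples.

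In the average over both ages 5 lists passed, 4 of them among the 5 of P0. Microglial genes were higher by 0.33 ± 0.20, with all 18 members above 0 (camera adjusted p = 0.000108, and adjusted p = 0.71 with an estimated correlation). C1qb was at 0.52 and Cd68 at 0.55, and 2 members passed over the list alone. Meninges, pericyte and fibroblast genes were higher by 0.26 ± 0.20 (adjusted p = 0.000108, and adjusted p = 0.278 with an estimated correlation), with Ptgds at 0.52 and 6 members passing over the list alone. Red blood cell genes were higher by 0.48 ± 0.52 (adjusted p = 0.035, and adjusted p = 0.71 with an estimated correlation), with Hbb-b2 at 1.09 and 2 members passing over the list alone. Voltage-gated ion channels were lower by -0.07 ± 0.15 (adjusted p = 0.0222, and adjusted p = 0.287 with an estimated correlation), with Scn1a at -0.24. GABA and glycine receptor subunits were lower by -0.10 ± 0.16 (adjusted p = 0.035, and adjusted p = 0.278 with an estimated correlation), with Gabrg3 at -0.34. Of these 5 lists, 0 members changed over all genes. The number of lists was 8 without P0 wild-type sample 1, 2 without P0 wild-type sample 2, and 3 without P0 knockout sample 3 or P5 knockout sample 2. Oxidative phosphorylation, not among the 5 lists, passed with array weights (mean 0.24, camera adjusted p = 0.00301). It was at 0.21 without P0 wild-type samples 1 and 2. A fit without P0 wild-type samples 1 and 2 was chosen after seeing the data, and the 1 P0 wild-type sample left is assumed to vary like the others. There meninges (0.16, adjusted p = 0.244), red blood cells (0.54, 0.0986), voltage-gated channels (-0.03, 0.344) and GABA and glycine receptors (-0.09, 0.193) did not pass, and microglia did (0.41, 5.83e-05). With fry 0 lists passed.

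The genotype difference was not shown to depend on age for any single gene. The interaction gave 0 changed genes in limma, with 629 genes at an unadjusted p under 0.05, where chance gives 630, and 209 changed genes without P0 wild-type sample 2. With array weights, which count variable arrays less, 1528 genes passed. The weights of P0 wild-type samples 1, 2 and 3 were 0.36, 0.19 and 2.44, so P0 wild type there rests mostly on sample 3. The smallest p belonged to Pdpn, a glycoprotein of leptomeninges and choroid plexus, at -1.14 (SE 0.23), followed by Apod at -1.0, Igf2 at -0.94, the adhesion receptor Adgrl3 at 0.77 and Tgds at -0.98, each with an adjusted p of 0.742. As lists, the genotype difference was smaller at P5 than at P0 for meninges, pericytes and fibroblasts by -0.31 ± 0.47 (23 members) and for oxidative phosphorylation by -0.33 ± 0.26 (28 members), both with a camera adjusted p of 0.047 and with adjusted p = 0.918 with an estimated correlation. Adjusted over the list alone, 5 meningeal members were lower and 0 of oxidative phosphorylation. With fry 0 lists passed. The meningeal list kept its call only without P0 wild-type sample 1 or 3, P0 knockout sample 3, P5 wild-type sample 1 or P5 knockout sample 1, and oxidative phosphorylation only without P0 wild-type sample 2 or P0 knockout sample 1. Without P0 or P5 knockout sample 2 the red blood cell list passed in their place (adjusted p = 0.0172 and 0.0169), and 0 lists passed without P5 wild-type sample 2 or 3 or P5 knockout sample 3. Across genes, which are not independent replicates, the genotype differences at P0 and at P5 correlated at Pearson's r = 0.152 and Spearman's rho = 0.101. That r was 0.0606 without P5 knockout sample 3, 0.101 without P0 wild-type sample 2, 0.106 without P5 wild-type sample 3 and 0.213 without P5 knockout sample 1.

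Between P0 and P5 in wild type, most genes of the myelin, proliferation and cerebellar granule cell lists rose and most Hox genes fell. The 10 largest rises were Mfap4, an extracellular matrix glycoprotein (48.5-fold), Pcp2, a Purkinje cell protein (43-fold), the myelin proteins Mobp (30.2-fold), Mog (18.8-fold) and Mag (8.94-fold), Sgo1, which protects centromere cohesion (8.22-fold), the neurogenic transcription factor Neurod1 (8.09-fold), the interferon-inducible Mndal (8.01-fold), Ugt8a, which makes the myelin lipid galactocerebroside (7.35-fold), and Ccnd2, a D-type cyclin (7.09-fold). For Mag the log2 level rose from 9.92 ± 0.19 to 13.08 ± 0.10 (SD, n = 3 each; difference 3.16, SE 0.16, adjusted p = 9.97e-08), and for Pcp2 from 8.31 ± 0.47 to 13.73 ± 0.15 (difference 5.43, SE 0.46, adjusted p = 1.36e-05). The 10 largest falls were Cldn34c1 (10.6-fold), Pex5l (3.73-fold), the pseudogene Pisd-ps3 (3.31-fold), Hoxd10 (3.13-fold), Dcx, a microtubule protein of young neurons (3.1-fold), Pax8 (2.97-fold), Hoxd9 (2.85-fold), Zfp558 (2.79-fold), Gbx1 (2.78-fold) and the proteoglycan Gpc2 (2.75-fold), with adjusted p from 3.51e-05 for Gpc2 to 0.0383 for Cldn34c1. Cldn34c1 was at 11.80 ± 0.08 in P0 and 8.39 ± 2.39 in P5 wild type, and it lost its call without P0 wild-type sample 1 or 3, P0 knockout sample 2 or P5 wild-type sample 1 or 2 (adjusted p 0.0501 to 0.157). Without P0 wild-type samples 1 and 2 together, which leaves 1 P0 wild-type sample, Cldn34c1 (0.138), Pex5l (0.0619), Hoxd9 (0.0689) and Gbx1 (0.0555) did not pass. Mfap4 (6.39 ± 1.18), Mog (7.37 ± 0.57), Sgo1, Mndal and Pcp2 at P0 and Cldn34c1 at P5 had mean log2 levels under the 8.72 of the filter, which were not shown to be above background. The size and order of these folds are therefore uncertain. Dim probe sets of Mobp and Pax8 had the opposite sign without passing, at -0.06 and 0.61. In all, 2438 genes changed, 1363 higher and 1075 lower, and 570 of them by 2-fold or more, 486 higher and 84 lower. Of the 2438, 2369 separated the ages completely.

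**Figure D3:**
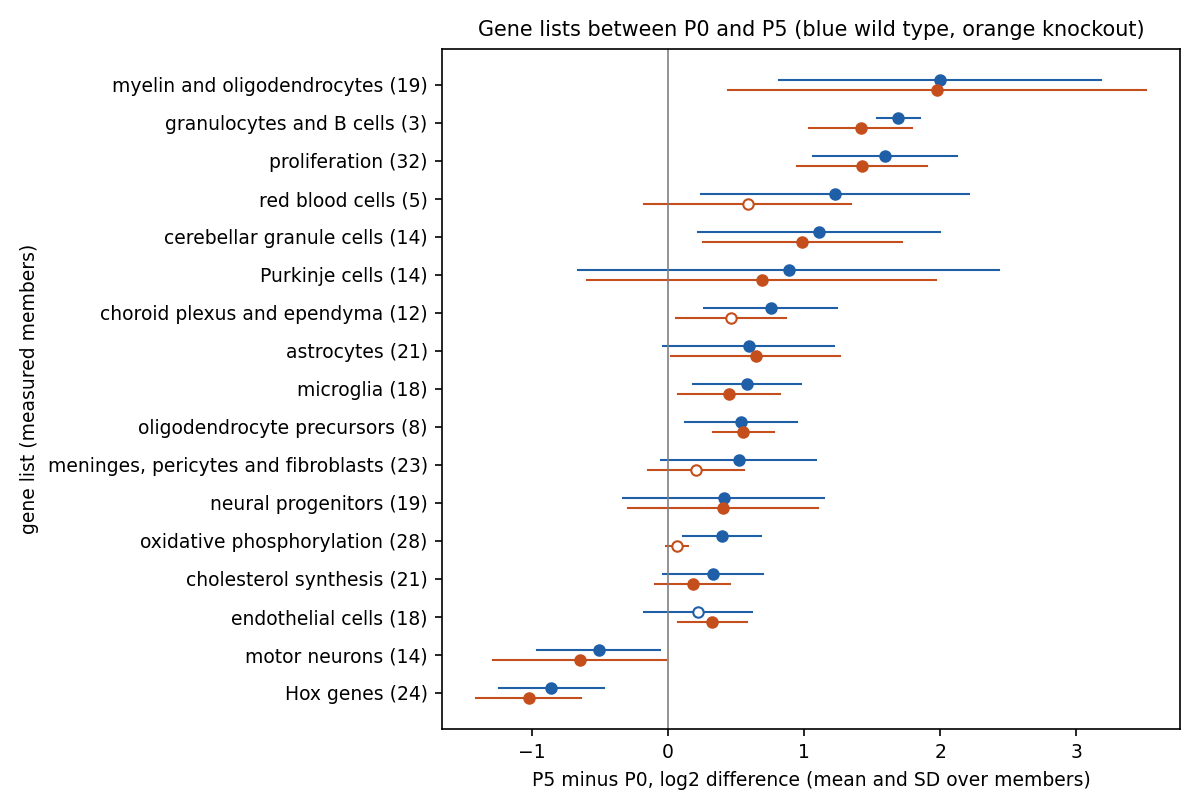
Mean P5 minus P0 log2 difference of the 17 gene lists that passed camera in either genotype, with bars of 1 SD over members and the number of measured members in brackets. Blue is wild type and orange knockout, filled points passed at the preset correlation and open points did not; myelin lies at 2.0 and 1.98 and Hox genes at -0.85 and -1.02.

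In wild type, myelin and oligodendrocyte genes were higher at P5 by 2.0 ± 1.18, with 18 of 19 members rising, 19 when adjusted over the list alone, and a camera adjusted p of 2.63e-18 (adjusted p = 0.0429 with an estimated correlation). Astrocyte genes were higher by 0.60 ± 0.63 with 11 of 21 rising, 14 over the list alone (adjusted p = 3.92e-05, and adjusted p = 0.0395 with an estimated correlation). Among them the intermediate filament Gfap rose 3.94-fold and the water channel Aqp4 1.85-fold. Proliferation genes were higher by 1.60 ± 0.53 with 30 of 32 rising, 32 over the list alone (adjusted p = 1.06e-26, and adjusted p = 0.0575 with an estimated correlation), such as Mki67 by 4.44-fold and Top2a by 3.93-fold. Cerebellar granule cell genes were higher by 1.11 ± 0.89 with 11 of 14 rising, 12 over the list alone (adjusted p = 1.94e-08, and adjusted p = 0.0575 with an estimated correlation), among them the granule lineage transcription factors Pax6 by 4.18-fold and Atoh1 by 4.46-fold. Purkinje cell genes were higher by 0.89 ± 1.55 with 6 rising, 1 falling and 7 not past the threshold, and 6 and 2 over the list alone (adjusted p = 0.0182, and adjusted p = 0.182 with an estimated correlation). Calb1 rose 3.75-fold and Car8 4.3-fold. Oligodendrocyte precursor genes rose in 5 of 8 members, 5 over the list alone (mean 0.54 ± 0.41, adjusted p = 0.00549, and adjusted p = 0.0716 with an estimated correlation), with Gpr17 at 2.49-fold. Hox genes, which specify position along the hindbrain and spinal cord, were lower by -0.85 ± 0.38, with 16 of 24 falling, 17 over the list alone, and 0 rising (adjusted p = 4.47e-11, and adjusted p = 0.178 with an estimated correlation). Without P0 wild-type samples 1 and 2, with the 1 sample left assumed to vary like the others, the Hox mean was -0.46 (adjusted p = 0.000496). Motor neuron genes were lower by -0.51 ± 0.45 with 5 of 14 falling, 8 over the list alone (adjusted p = 0.000615, and adjusted p = 0.0575 with an estimated correlation), such as the intermediate filament Prph by 2.41-fold and Isl1 by 2.37-fold.

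Transcripts of other tissues moved with age in wild type as well. Meninges, pericyte and fibroblast genes were higher by 0.52 ± 0.57 with 10 of 23 rising, 11 over the list alone (camera adjusted p = 0.0011, and adjusted p = 0.191 with an estimated correlation), with Igf2 at 2.81-fold and Ptgds at 2.3-fold. Microglial genes were higher by 0.58 ± 0.40 with 8 of 18 rising (adjusted p = 0.00103, and adjusted p = 0.496 with an estimated correlation), with P2ry12 at 1.99-fold; over the list alone 10 were higher and 1 lower. Red blood cell genes were higher by 1.23 ± 0.98 with 3 of 5 rising, 3 over the list alone (adjusted p = 0.00549, and adjusted p = 0.303 with an estimated correlation), with the anion exchanger Slc4a1 at 6.11-fold. The other lists past the threshold, all higher, were cholesterol synthesis (mean 0.33, 5 of 21 rising, adjusted p = 0.0182, and adjusted p = 0.509 with an estimated correlation), choroid plexus and ependyma (0.76, 3 of 12, 0.0328, and adjusted p = 0.509 with an estimated correlation), granulocytes and B cells (1.69, 2 of 3, 0.0182, and adjusted p = 0.303 with an estimated correlation), neural progenitors (0.41, 7 rising and 2 falling of 19, 0.0328, and adjusted p = 0.177 with an estimated correlation) and oxidative phosphorylation (0.40, 2 of 28, 0.00549, and adjusted p = 0.525 with an estimated correlation). Adjusted over the list alone, 6, 4, 3, 8 and 0 members were higher in that order, with 2 neural progenitor genes lower. Without P0 wild-type samples 1 and 2, with 1 P0 wild-type sample left that is assumed to vary like the others, the lists of meninges (adjusted p = 0.153), choroid plexus (0.461), cholesterol synthesis (0.054), granulocytes and B cells (0.0972) and Purkinje cells (0.121) did not pass. The Xist transcript, which marks female tissue, had a signal of 18340 and 24930 in P0 wild-type samples 1 and 2 and of 17.52 to 238.6 in the other wild-type samples, so the sexes were not balanced between the ages. With Xist as a covariate 1916 genes changed, 1743 of them among the 2438. The count was 4825 without P0 wild-type sample 2, 1346 and 1442 without P0 wild-type samples 1 and 3, and 1200, 1227 and 1242 without P5 wild-type samples 1, 2 and 3. It was 3046 without P0 wild-type samples 1 and 2 together, where the P0 side is 1 sample.

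In the knockout samples, most genes of the proliferation, myelin and granule cell lists rose and most Hox genes fell between P0 and P5. The 10 largest rises were Mog (62.9-fold), Mobp (40.9-fold), Mfap4 (20.2-fold), Pcp2 (19.8-fold), Mag (9.52-fold), Mndal (8.75-fold), Insm1, a zinc finger factor of newborn neurons (8.74-fold), Ugt8a (7.8-fold), Esco2, an acetyltransferase of cohesin (6.62-fold), and Neurod1 (5.73-fold). For Mag the log2 level rose from 9.62 ± 0.25 to 12.87 ± 0.17 (SD, n = 3 each; difference 3.25, SE 0.16, adjusted p = 6.86e-08). The 10 largest falls were Isl1 (4.7-fold, from 11.16 ± 0.32, adjusted p = 5.2e-05), Zfp991 (3.66-fold), Scube3 (3.48-fold), G630016G05Rik (3.39-fold), Hoxd10 (3.35-fold), Cul9 (3.19-fold), Gbx2, a factor of the midbrain and hindbrain border (3.18-fold), the exosome subunit Exosc9 (2.91-fold), Stag3 (2.75-fold) and Hoxb5 (2.75-fold). Mog (5.47 ± 1.35), Mfap4 (7.94 ± 1.15), Mndal and Esco2 at P0 and Scube3, G630016G05Rik and Cul9 at P5 had mean log2 levels under the 8.72 of the filter, which were not shown to be above background. The size and order of these folds are therefore uncertain. Other probe sets of Mobp, Cul9 and Zfp991 had the opposite sign without passing, at -0.40, 0.41 and 0.59. Scube3 lost its call without P0 knockout sample 2 or 3 or P5 knockout sample 1 (adjusted p 0.0575 to 0.0722), and Cul9 without P0 knockout sample 2 or 3 or P5 knockout sample 2 (0.0509 to 0.0651). In all, 1314 genes changed, 692 higher and 622 lower, 351 of them by 2-fold or more, and 1311 separated the ages completely.

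Proliferation genes in knockout were higher at P5 by 1.43 ± 0.48 with 30 of 32 rising, 31 over the list alone (camera adjusted p = 1.72e-34, and adjusted p = 0.0227 with an estimated correlation), with Top2a at 4.56-fold. Myelin genes were higher by 1.98 ± 1.53 with 17 of 19 rising, 17 over the list alone (adjusted p = 4.78e-24, and adjusted p = 0.0184 with an estimated correlation), with Cnp at 3.02-fold. Granule cell genes rose in 9 of 14 members, 12 over the list alone (mean 0.99 ± 0.73, adjusted p = 1.46e-11, and adjusted p = 0.0227 with an estimated correlation), with Pax6 at 4.05-fold. Astrocyte genes rose in 9 of 21, 12 over the list alone (mean 0.65 ± 0.62, adjusted p = 3.16e-09, and adjusted p = 0.00487 with an estimated correlation), with Gfap at 4.34-fold and the glutamate transporter Slc1a2 at 1.91-fold. Oligodendrocyte precursor genes rose in 5 of 8, 6 over the list alone (mean 0.56 ± 0.23, adjusted p = 6.8e-05, and adjusted p = 0.0227 with an estimated correlation), with Gpr17 at 1.85-fold. Purkinje cell genes rose in 5 of 14, 5 over the list alone (mean 0.69 ± 1.28, adjusted p = 0.00814, and adjusted p = 0.118 with an estimated correlation), with Calb1 at 3.3-fold. Endothelial genes rose in 3 of 18, 3 over the list alone (mean 0.33 ± 0.25, adjusted p = 0.000241, and adjusted p = 0.192 with an estimated correlation), with the tight junction protein Cldn5 at 1.34-fold. Microglial genes rose in 4 of 18, 6 over the list alone (mean 0.45, adjusted p = 0.000241, and adjusted p = 0.52 with an estimated correlation), with P2ry12 at 2.33-fold. Neural progenitor genes rose in 4 of 19 (mean 0.40, adjusted p = 0.00812, and adjusted p = 0.0664 with an estimated correlation), cholesterol synthesis genes in 2 of 21 (0.18, 0.0451, and adjusted p = 0.654 with an estimated correlation) and granulocyte and B cell genes in 1 of 3 (1.42, 0.0101, and adjusted p = 0.296 with an estimated correlation). Over the list alone, 4, 2 and 3 of these were higher in that order, with 2 neural progenitor genes lower. Hox genes fell in 17 of 24, 19 over the list alone (mean -1.02 ± 0.39, adjusted p = 8.84e-15, and adjusted p = 0.0959 with an estimated correlation), with Hoxc4 at 2.62-fold. Motor neuron genes fell in 5 of 14, 9 over the list alone (mean -0.64 ± 0.64, adjusted p = 4.9e-05, and adjusted p = 0.0228 with an estimated correlation), with Slc18a3 at 1.95-fold. The Xist signal was 16450, 20890 and 21370 in P0 knockout samples 1 and 2 and P5 knockout sample 2 and 21.26 to 89.82 in the others, and 1103 genes changed with Xist as a covariate, 1017 of them among the 1314. The count of changed genes was 800, 649 and 694 without P5 knockout samples 1, 2 and 3.

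Of 17 lists past camera for age in 1 or both genotypes, 12 passed in both. Meninges, red blood cells, choroid plexus and oxidative phosphorylation passed only in wild type and endothelial genes only in knockout, with an interaction adjusted p of 0.047, 0.0861, 0.638, 0.047 and 0.614 in that order (0.918 for each with an estimated correlation). With fry 18 lists passed in wild type and 12 in knockout, and choroid plexus (0.0971) and oxidative phosphorylation (0.107) in wild type and cholesterol synthesis (0.203) and microglia (0.0983) in knockout did not. Across 12600 genes the P5 minus P0 differences in wild type and knockout correlated at Pearson's r = 0.748 and Spearman's rho = 0.663, with no sample shared between them. The genes changed in both numbered 939, all with the same sign. Of these 555 were higher and 384 lower, where independent lists of the same lengths would share 74.9 and 53.1. Of the genes changed in wild type, 97.1% had the same sign in knockout. That r was 0.614 without P0 knockout sample 1 and 0.659 without P0 wild-type sample 2. The interaction, which tests the difference between the genotypes, passed for 0 genes.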

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

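The tests of linked DNA, of the Grin3b neighbourhood, of sample labels, developmental stage and other tissue at P0, and of Hox against monoamine neuron genes were chosen only after the result was seen, the Hox paralog test was written after the fall of the Hox list was known but before its own value, and the splits were fixed before.

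Some results stood out in data outside the gene tests. Probe set 1444198_at, which has no gene symbol, differed by -5.06 on the log2 scale between knockout and wild type averaged over both ages (SE 0.41, 33.3-fold, adjusted p = 0.000141), with signals of 14675 ± 558 in P0 wild type, 1110 ± 1355 in P0 knockout, 11985 ± 944 in P5 wild type and 226 ± 69.6 in P5 knockout (SD, n = 3 each). The unnamed probe set 1457416_at differed by -1.77 (SE 0.25, 3.41-fold, adjusted p = 0.0463). A dim Trem2 probe set, 1421792_s_at, which reads a receptor of microglia, was 2.48 higher in P0 knockout (SE 0.34, 5.56-fold, adjusted p = 0.0473), with signals of 94.3 ± 24.8 and 582 ± 139, and a second Trem2 probe set was at 1.40 (SE 0.76). These folds are uncertain in size, since the level of Trem2 in P0 wild type (6.76), of 1444198_at in P5 knockout (7.91) and of 1457416_at in both knockout groups (8.64 and 8.34) lies under the 8.72 of the filter. The genotype difference of whole lists differed between the ages for meninges, pericytes and fibroblasts by -0.31 and for oxidative phosphorylation by -0.33, with a camera adjusted p of 0.047 for each and adjusted p = 0.918 with an estimated correlation. Neither passed without P5 wild-type sample 2 or 3, P5 knockout sample 2 or 3 or P0 knockout sample 2, and without each other sample 1 of them did.

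Tmem259, the brightest probe set of Rmst and 1444198_at were far lower in the knockout samples at both ages. Lower expression of the whole Grin3b neighbourhood is argued against, since the median difference of its other 52 measured neighbours was 0.107 (95% bootstrap interval 0.0667 to 0.134). DNA linked to the targeted gene, anywhere on its chromosome, was tested first: of the 50 genes with the smallest p, leaving out Grin3b, Tmem259, Rmst and Gm3515, 5 lay on that chromosome where 2.49 were expected (one-sided Fisher exact p = 0.102), which cannot tell. A search for a dense run of such genes was chosen after that value was seen and tried in 6 settings, of which the setting printed has the smallest p: of the 100 genes with the smallest p, 8 lay within a run of 100 tested genes on the chromosome of Grin3b, against a median of 4 in random orders and at most 6 on another chromosome (permutation p = 0.0015, one-sided, and 0.0015 to 0.0345 over the settings, in 2 of which another chromosome held as many). The run holds Rmst but not Grin3b, and of the 8 genes, which leave out Rmst, 5 were higher, 3 lower and 0 called, so DNA linked to the targeted gene that differs between the genotypes may contribute and stays a hypothesis. Whether the Tmem259 difference comes from the deletion reaching Tmem259, from its probes or from linked DNA cannot be decided without the deleted part of Grin3b and the probe positions, which were not used here.

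At P0 2032 genes had an unadjusted p under 0.05 and 3 passed the adjusted threshold, but with only the P0 samples in the fit 755 had such a p, against 630 by chance, so a shift of many genes between the genotypes is not shown. Swapped labels are argued against by Tmem259, which the P5 samples alone pick out (adjusted p = 3.41e-07 with only these in the fit, against 3.41e-07 to 0.138 over 27 alternatives), since its lowest signal of the P0 wild-type samples was 7.57 times the highest of the P0 knockout samples. A difference in developmental stage between the P0 genotypes was not decided, since the test is void for a difference of group means: across genes the first component of the within-group deviations correlated with the mean P5 minus P0 difference at r = 0.351, with P0 wild-type sample 2 on the side of P5, but that component is taken after the group means are removed. On the first principal component of all samples, which parts the ages, P0 knockout lay at -31.2, -5.5 and -7.6. P0 wild type lay at -49.0, -12.8 and -37.1. Knockout samples 2 and 3 thus lay nearer P5 than any wild-type sample, while knockout sample 1 lay among the wild-type samples. Each knockout sample lay nearer P5 than the wild-type sample of the same number. This shift was not tested. The 4 lists higher in P0 knockout also rose with age in wild type. Both comparisons share the P0 wild-type samples, and the myelin and proliferation lists did not pass at P0. Carry-over of other tissue cannot be told apart from the genotype, because red blood cell (0.80), meningeal (0.41) and choroid plexus (0.36) markers were higher in the knockout samples while endothelial markers were at -0.0405 (SE 0.0664 over members), and without P0 wild-type samples 1 and 2, with 1 P0 wild-type sample left that is assumed to vary like the others, choroid plexus was at -0.04 (adjusted p = 0.824), meninges at 0.22 (0.576) and red blood cells at 0.92 (0.072). Without P0 wild-type sample 2 the count was 2696, without sample 1 it was 5, and without P0 knockout sample 2, P5 wild-type sample 1 or 2 or P5 knockout sample 1 or 2 it was 1.

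Hox genes were lower and proliferation and granule cell genes higher at P5 in both genotypes. A smaller share of spinal cord in the P5 tissue stays open as a cause of the Hox fall. Hox genes of paralog groups 8 to 11 differed from those of groups 1 to 4 by 0.144 (SE 0.162, two-sided permutation p over genes = 0.426), with means of -0.91 over 10 genes and -1.06 over 8. A larger fall in groups 8 to 11 was thus not seen. This cannot decide the question, since the part of each set's signal that comes from spinal cord is not known. The genes are also not independent replicates. Motor neuron genes, which also mark spinal cord, were at -0.51 in wild type and -0.64 in knockout. A smaller share would give such a fall, but so would dilution or a developmental change, and these were not told apart. The same dilution of every older cell population was not decided. The Hox mean lay -0.856 (SE 0.172) from that of monoamine neuron genes, at -0.94 and -0.08, more than the 0.3 set for dilution. The monoamine list is no clean reference, since its 16 genes differed (SD 0.62), with En2 rising and Lmx1b falling. Its genes are not independent replicates either. Without P0 wild-type samples 1 and 2, with 1 P0 wild-type sample left, the wild-type means were -0.46 and -0.23, closer than 0.3. In knockout they were -1.02 and -0.10. Dilution therefore stays open in both genotypes. A developmental fall of Hox transcripts stays open as a hypothesis, as does a change in the share of other parts of the tissue.

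Other splits of the same samples were counted beside each number of changed genes. Knockout minus wild type at P0 gave 3 genes, 3 of the 10 splits gave as many, and the highest other split gave 3390. That split sets P0 wild-type samples 1 and 3 and P0 knockout sample 1 against the others, which points to a structure of the samples other than genotype. At P5 the count was 1, 2 of 10 splits gave as many and the highest other gave 1. For age in wild type the count was 2438 in 1 of 10 splits, with at most 0 in another, and in knockout 1314 in 1 of 10, with at most 0 in another. These 10 splits are too few for a share under 0.05. For the average over both ages, 10 of 100 within-age splits drawn from 200 gave 3 genes or more, with a highest other of 1875, so chance was not excluded, and for the interaction, with 0 genes, all 100 did by construction, which tells nothing about chance, with a highest other of 1685.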

How the results depend on the processing

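The covariate from the first within-group component and the fit without P0 wild-type samples 1 and 2 were chosen after seeing the data, and every other alternative was fixed before. The fit without these samples leaves 1 P0 wild-type sample, which is assumed to vary like the samples of the other groups. That sample was low in Xist, unlike P0 knockout samples 1 and 2, so sex is not balanced there between the P0 genotypes. The covariate is taken from the within-group deviations of the same samples. It leaves every group difference unchanged and lowers the spread left in the fit, so counts that rise with it are no support. No named gene and no list past the threshold, in the fit reported or in an alternative, changed sign between them, while some lists that passed in neither did, such as choroid plexus with knockout minus wild type at P0, at 0.36 and at -0.04 without P0 wild-type samples 1 and 2. The sign of other genes was not compared. Over the alternatives, named genes that had passed kept their call in 1171 comparisons and lost it in 99, and lists that had passed kept it in 894 and lost it in 165. Most of these genes were named for age, and the genotype calls other than Tmem259 were less stable. At P0 Hnrnpl kept its call in 16 of 28 alternatives and Apod in 14 of 28. Averaged over both ages Hnrnpl kept it in 14 of 26 and Rmst in 12 of 26. Tmem259 kept it in 26 of 28 at P0, 20 of 27 at P5 and 26 of 26 averaged. The scaling alternatives moved the median of all genes by less than 0.1, and the cause of the differences below was not tested except where a setting leaves out samples. Array weights were 0.36, 0.19 and 2.44 for P0 wild-type samples 1, 2 and 3. Counts with array weights that involve P0 wild type therefore rest mostly on sample 3 of that group.

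The P0 count of 3 genes for knockout minus wild type was 1 with each probe set on its own, 0 with only the groups compared, 1 with eBayes without trend, 3092 with array weights, 9 with the replicate block, 1 with Xist as a covariate, 0 with a t-test with equal variances, 2017 with the first residual component as a covariate and 564 without P0 wild-type samples 1 and 2. The P5 count of 1 was 6 with only the groups compared, 6 with array weights, 2 with the t-test and 2 with the residual component. The count of 3 averaged over both ages was 1 with each probe set on its own, 2041 with array weights, 5 with the replicate block, 1 with Xist as a covariate, 687 with the residual component and 45 without P0 wild-type samples 1 and 2. Whether the numbers pair the P0 samples is open. Same-numbered P0 samples of the genotypes correlated at 0.414, 0.378 and 0.0276, and wild-type samples 1 and 2 were closest to the knockout sample of the same number. In both genotypes P0 samples 1 and 2 were also high in Xist and sample 3 low. Same-numbered P5 samples correlated at -0.108, -0.128 and -0.126, which gives no sign of a pairing. The block stands only as an alternative.

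For age, the wild-type count of 2438 was 1315 with only the groups compared, 6015 with array weights, 291 with the t-test and 4737 with the residual component, and the knockout count of 1314 was 2107, 293 and 2678 with array weights, the t-test and the residual component. The interaction count of 0 was 1528 with array weights and 399 with the residual component. The correlation of the genotype differences of 0.152 was 0.0487 with no filter on dim probe sets, and that of the age differences of 0.748 was 0.447 with no filter and 0.690 with each probe set on its own.

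Gene lists past camera with knockout minus wild type at P0 numbered 5, against 0 with the correlation estimated per list, 3 with no filter, 3 with a filter at the 60th percentile, 2 with array weights and 3 without P0 wild-type samples 1 and 2. At P5 the 4 lists were 0 with an estimated correlation and 2 with no filter. Averaged over both ages the 5 lists were 0 with an estimated correlation, 3 with the 60th percentile, 2 with array weights and 2 without P0 wild-type samples 1 and 2. The 16 lists for age in wild type were 2 and the 13 in knockout were 6 with an estimated correlation. The 2 lists of the interaction were 0 with an estimated correlation and 1 each with the authors' scaling only, array weights, the replicate block and the residual component. A list with no members left under a filter has no value there.

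Leaving out each sample in turn gave 1 to 2696 genes for knockout minus wild type at P0, 0 to 3 at P5 and 1 to 752 averaged over both ages. It gave 1200 to 4825 for age in wild type, 649 to 1965 in knockout and 0 to 209 for the interaction. The highest values came without P0 wild-type sample 2, except at P5, where it was P0 knockout sample 3. The correlations ranged from 0.0606 to 0.213 for genotype and from 0.614 to 0.771 for age. Lists numbered 1 to 5 at P0, 1 to 7 at P5, 2 to 8 averaged, 11 to 17 for age in wild type, 12 to 14 in knockout and 0 to 1 for the interaction. Grin3b ranged from -2.55 to -1.87 at P0, from -1.87 to -1.51 at P5 and from -2.15 to -1.81 averaged. Its signal is dim, and for dim probe sets background limits what can be read.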

Other observations

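Single neurotransmitter genes changed with age, while most members of their lists did not and the lists did not pass camera. With fry the GABA and glycine (adjusted p = 0.00254) and the AMPA, kainate and delta receptor lists (0.0212) passed in wild type. In wild type 4 of 14 GABA and glycine receptor subunits fell from P0 to P5 and 0 rose, with 5 lower when adjusted over the list alone (list fixed before the data were examined; camera adjusted p = 0.128). The glycine receptor subunit Glra2 fell 1.84-fold (log2 difference -0.88, SE 0.15), and Gabra3, Gabra5 and Gabrg3 differed by -0.54, -0.47 and -0.62. In knockout Glra2 fell 1.71-fold and Gabra3 1.39-fold, and Glrb rose 1.44-fold (camera adjusted p = 0.954). Of 15 AMPA, kainate and delta receptor genes 2 fell in wild type, Grik1 by 2-fold and Cacng3 by 1.5-fold, and in knockout Grik1 fell 1.38-fold, with 4 lower in wild type and 1 higher and 2 lower in knockout over the list alone. Synaptic vesicle genes split in wild type, with 3 rising and 5 falling of 24, among them Syn3 at -0.80, the active zone protein Pclo at -0.70 and Syt11 at 0.71, and in knockout 4 fell, Syn3, Pclo, Bsn and Stx1a. Over the list alone 4 were higher and 6 lower in wild type and 2 and 4 in knockout.

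Ion channel and immature neuron genes went both ways as well. Of 17 voltage-gated channel genes 3 rose and 2 fell in wild type, with Kcna1 at 1.91-fold and Scn2b at 1.83-fold higher and Scn3a at 1.64-fold lower, and in knockout 3 rose and 4 fell, with 3 and 4 in wild type and 4 and 4 in knockout over the list alone. Of 29 genes of immature neurons and axon growth 7 rose and 10 fell in wild type, with a mean of 0.01, a median of -0.27 7 higher and 14 lower over the list alone and a camera direction below 0 (adjusted p = 0.128), and the transcription factors Nhlh1 and Nhlh2 were 2.76-fold and 2.19-fold higher. In the postsynaptic density list Nlgn3 fell 1.53-fold in wild type and 1.49-fold in knockout, and Homer2 rose 1.47-fold and 1.86-fold. In the list of monoamine neurons En2, a gene of the midbrain and cerebellum, rose 2.06-fold in wild type and 2.11-fold in knockout, and Lmx1b fell 1.88-fold and 1.92-fold.

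Transcripts of the sex chromosomes differed between samples within groups. The Y-linked Eif2s3y had a signal of 6934 in P0 wild-type sample 3 and 7366 in P0 knockout sample 3, against 5.072 to 190.1 in the other P0 samples. At P5 it was 4959 to 5971 in all samples but P5 knockout sample 2, where it was 73.99. The list of 4 sex-linked genes did not pass camera in any comparison (adjusted p 0.549 to 0.873), with 0 members changed. This says nothing about the balance of the sexes, since Xist and the Y-linked genes of the list move in opposite directions with sex.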
